A study of Homo sapiens with 8 samples.

How the data were processed

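The samples were 8 human RNA extracts, 1 from each of 4 transfections in primary bronchial epithelial cells (HBEC, number 1 in the sample titles) and in the BEAS2B line (number 2). Per the labels, cells were transfected at 30 nM for 24 h, and 100 ng of RNA was labelled with Cy3 for a SurePrint G3 Human GE v3 array of Agilent, with 1 array per sample. Per the file headers and the submitters' processing notes, the authors scanned the arrays and read them with Agilent Feature Extraction 11.5.1.1, whose processed signal is an intensity with the background subtracted and spatial trends removed, before any scaling between arrays. The deposited files also hold the mean signal of each spot and its local background as intensity, and a flag for spots well above background. The authors also deposited a table on the log2 scale. Set against each array's own signals, its columns had a correlation of 1.0 and at least 99.97% of values within 0.02 of log2 of the processed signal minus the 75th percentile of the array; column medians lay between -3.92 and -3.75, and nothing was centred by gene. All arrays came from 1 slide and 1 scan, where the 2 rows of the slide held 1 cell type each and its 4 columns 1 transfection each, so position cannot be told apart from either.

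Values here are log2 of the processed signal minus the 75th percentile of each array over 58201 probes, after control spots and 475 outlier spots were left out; spots of 1 probe were averaged, and 0 spots were saturated. Between 48.5% and 50.9% of probes were well above background on an array. The number of arrays, not a depth of counting, limits the precision. Of the probes, 31104 were named through their accession, 3366 through their symbol and 496 through an older symbol in a table of RefSeq gene names, and 23235 kept the name in the file. 180 probes of Y-linked genes, XIST or TSIX were left out of all tables, while other X-linked genes were kept. Probe positions are those of the files (hg19); exons and UTRs were not annotated here. A probe entered if it was well above background on at least 2 of the 8 arrays, and the brightest such probe stood for its gene, which left 24908 genes, 8328 of them with identifiers that are counted but not named and 5753 with more than 1 probe. Where a probe was not well above background on any array of a group, the fold is given as a bound: the bright group's mean against the mean, per array, of the higher of the lowest signal well above background and the probe's own signal. Bounds within 1 cell type use the same rule on single arrays.

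Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on all 8 arrays, with transfection and cell type as terms, 3 residual degrees of freedom), and Benjamini-Hochberg adjusted p under 0.05 was the threshold. The fit holds the number of the sample title as a replicate block, because that number stands for the cell type. Samples of the same number did deviate together from their transfection means: the correlation of their deviations was at least 0.905 over the 12 pairs, which with 2 samples per group mirrors between the numbers. Arrays of 1 cell type correlated at 0.97 to 0.987 and arrays of different cell types at 0.805 to 0.855. Gene lists, fixed before the data were examined from knowledge of airway cells, microRNA targets, mitochondria, senescence and stress, were tested with camera with a preset correlation of 0.01 and adjusted over 33 lists and 3 mimics, and for the cell types over 33 lists. None of the 12 calls for a mimic and none of the 15 calls between the cell types held with an estimated correlation; fry, which does not set a list against other genes, called 0 lists for each mimic and 27 between the cell types. Each list was also adjusted over the list alone.

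Named genes followed a rule fixed before the data were examined. For each mimic it took SIRT3, and the 10 genes that rose and the 10 that fell most among those that passed with the same sign in both cell types. Where fewer passed, genes with the largest smaller difference of the 2 cell types filled the places and are said not to have passed. For each list it took up to 4 members with the largest difference, and between the cell types the 10 largest in each direction. Which lists have their members named was chosen after the lists' values were seen. Counts of genes at least 2-fold the same way in both cell types are set against the product expected if the cell types were independent.

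The fit was tested on simulated data: of genes changed by 2 on the log2 scale, 61.4% were called in the comparison of miR-23b-3p, 59.2% in that of miR-145-5p, 50.7% in that of miR-494-3p and 61.4% between the cell types. At a change of 1 the shares were 10.3%, 7.5%, 14.3% and 33.9%, with 5 or 6 false calls in 24908 genes. Alternatives were another background correction (normexp, offset 50), quantile and median scaling, 2 other filters, the mean of a gene's probes, the deposited log2 table, no replicate block, only the 4 arrays of a comparison, a variance trend, other list tests, the other mimics as the reference and each array left out in turn. A planned search for seed sites in 3' UTRs was not run, as no genome was used here; published targets and a search of the probe sequences stand in for it.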

Results

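Gene expression was measured in primary human bronchial epithelial cells (HBEC) and in BEAS2B, an immortalised line of bronchial epithelial cells, 24 h after transfection. Each cell type received 30 nM of a negative control RNA or of a mimic of miR-23b-3p, miR-145-5p or miR-494-3p. A mimic is a short RNA duplex that carries the sequence of the mature microRNA. The 8 one-colour arrays held 1 array for each transfection in each cell type. Each transfection thus had 2 arrays and each cell type 4. Between 28220 and 29644 of 58201 probes were well above background on an array, and the 75th percentile of the processed signal lay between 102 and 131. The study is known for microRNAs that lung fibroblasts pass to bronchial epithelium in vesicles, with SIRT3, a mitochondrial deacetylase, as the target of interest of miR-23b-3p and miR-494-3p. Differences are log2 differences from the control transfection, given as the mean of the cell types with the standard error (SE) of the fit (n = 2 arrays per transfection). A p-value therefore sets the size of an effect against how far effects differed between HBEC and BEAS2B over all transfections. It does not measure how alike 1 effect was in the 2 cell types. No test was possible within a cell type, where each transfection had 1 array. With 1 array left out, the fit also draws on the cell type difference of the transfections that keep both arrays. Such a value is not the difference measured within the remaining cell type.

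The first question was which transcripts the miR-23b-3p mimic altered. HMGA2, a chromatin protein of embryonic tissues, was 2.93 ± 0.31 higher than in the control (7.62-fold). FOXQ1, a forkhead transcription factor, was higher by 2.47 in HBEC and at least 21.1-fold higher in BEAS2B. DDAH1, which breaks down methylated arginine, lay at -3.02 ± 0.29 (8.10-fold lower), and TLR3, a sensor of double-stranded RNA, at -2.30 ± 0.37. No gene passed the test: limma called 0 of 24908 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.114. At an unadjusted p under 0.05 there were 3615 genes where 1245 were expected. By size alone, 253 genes were at least 2-fold higher in both cell types and 264 at least 2-fold lower. If the cell types were independent, 31.9 and 38.6 would be expected, and 55 genes moved at least 2-fold in opposite directions. In a simulation with the residual spread of these arrays, 218 genes given no change were at least 2-fold the same way, against 517 here.

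SIRT3 lay 0.44 below the control in HBEC (log2 difference -0.44) and at -0.48 in BEAS2B after miR-23b-3p, a mean of -0.46 ± 0.15 (adjusted p = 0.28). Its log2 signal in HBEC was 2.30, against 2.33 after miR-145-5p and 2.58 after miR-494-3p. In BEAS2B it was 2.68, against 3.02 and 3.00. Its probe maps to chromosome 11, 216148 to 216207 (hg19), and a second SIRT3 probe gave -0.35. Among the other sirtuins, SIRT6 lay at 0.45, SIRT7 at 0.47 and SIRT5 at -0.34. Of 7 members 0 rose or fell, over all genes or adjusted over the list alone. Further genes above the control in both cell types were SLC36A1, a lysosomal amino acid transporter, at 2.36 ± 0.21, and CALU, a calcium-binding protein of the secretory pathway, at 2.48. CCND3, a G1 cyclin, lay at 2.31, LZTFL1 at 2.21, TRIQK at 2.18, PTPMT1, a mitochondrial phosphatase, at 2.16, and BANF1, which binds DNA at the nuclear envelope, at 2.10. SLC36A1, CALU, CCND3, LZTFL1, PTPMT1 and BANF1 were at least 2-fold higher in both cell types after the other 2 mimics as well, and against the mean of those PTPMT1 lay at -0.11. CCNA1 was at least 3.50-fold higher, as its probe was not well above background on either control array. Further genes below the control were FAM234B at -2.54, the small Cajal body RNAs SCARNA13 at -2.65 and SCARNA23 at -2.08. After the other 2 mimics, SCARNA13 was at least 2-fold lower in both cell types as well, and SCARNA23 was also below the control in both. A second SCARNA23 probe, well above background on 4 arrays, lay at 0.32. EDN2, an endothelin, lay at -2.42 ± 0.97, with -2.505 in HBEC and -2.336 in BEAS2B. In the fit without the HBEC array of the mimic EDN2 lay at -1.36. FER1L4 lay at -2.51 and the carbonic anhydrase CA9 at -2.16. KIF9 was at least 1.93-fold and IL7 at least 1.30-fold lower, both being not well above background on the mimic's arrays. The HMGA2 probe (chromosome 12, 66359789 to 66359848) stood apart from 2 other HMGA2 probes, at 0.23 and 0.00. The DDAH1 value comes from the brighter probe (chromosome 1, 85784474 to 85784533), and a dimmer one gave 0.12.

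Of 33 gene lists, 2 shifted relative to the other genes after miR-23b-3p (camera with a preset correlation of 0.01). Published targets of miR-145-5p, a microRNA not added to these samples, had a median of 0.33 (adjusted p = 0.00121; adjusted p = 0.966 with an estimated correlation). Of 39 members 0 passed over all genes, and 3 rose and 0 fell when adjusted over the list alone. Without the BEAS2B array of the mimic the median was 0.16 (adjusted p = 0.0308). DUSP6 lay at 1.17. NRAS lay at 1.92 ± 0.18 and was at least 2-fold higher after every mimic in both cell types, miR-145-5p included. Genes of the unfolded protein and integrated stress response had a median of 0.29 (adjusted p = 0.00404; adjusted p = 0.966 with an estimated correlation). SEL1L at 1.56, PDIA4 at 1.34 and HERPUD1 at 1.03 act in folding and degradation in the endoplasmic reticulum. These genes were also above the control after the other 2 mimics in both cell types. Of 30 members 0 rose over all genes and 1 when adjusted over the list alone. The list's median was 0.207 in HBEC and 0.423 in BEAS2B. Its call was lost without the HBEC array of the mimic (median 0.14) and without the BEAS2B control array (0.17). The median was 0.45 without the HBEC control array. Published targets of miR-23b-3p itself did not shift against the control: the median of 30 members was -0.05 (adjusted p = 0.548), and 0.03 under median scaling. Against the mean of the other 2 mimics it was -0.25 (adjusted p = 0.0472). After those mimics the list itself lay above the control, with medians of 0.07 (miR-145-5p) and 0.21 (miR-494-3p). Of the 30 members 0 passed over all genes after miR-23b-3p, and over the list alone 1 rose and 3 fell. MET, a receptor tyrosine kinase also at least 2-fold higher after every mimic, lay at 1.97, while APAF1, of the apoptosome, lay at -1.49, LDHB at -1.47 and CCNG1 at -1.02.

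Other lists of the question around SIRT3 gave values without a call against the control after miR-23b-3p. Mitochondrial antioxidants had a median of -0.11 (adjusted p = 0.282), with the peroxidase PRDX3 at -1.38 ± 0.16 in both cell types alike (-1.40 and -1.37). Over the list alone 1 of 13 fell, and the median was -0.22 without the BEAS2B control array. NRF2 and oxidative stress genes had a median of -0.23 (adjusted p = 0.061), with the transporters ABCC2 at -1.21 in HBEC and at least 1.81-fold lower in BEAS2B, and ABCC3 at -1.24. This list did pass under quantile normalization (adjusted p = 0.0387), median scaling (0.0493), no filter (0.0232) and with only the 4 arrays of the mimic and the control (0.0398). It also passed without the HBEC control array (0.035), the HBEC array of the mimic (0.0226) or either array of miR-145-5p (0.0411 and 0.0384), with medians between -0.28 and -0.12 over all arrays left out. The lowest median was that without the HBEC control array and the highest that without the BEAS2B array of the mimic. Glycolysis and hypoxia genes had a median of -0.04 (adjusted p = 0.319; 0.05 under median scaling), with ENO2 at -1.58, LDHB at -1.47 and ALDOC at -1.04. Without the BEAS2B array of the mimic this median was -0.13 (adjusted p = 0.0477), and without the HBEC array 0.02. Senescence-associated secreted factors had a median of 0.19 (adjusted p = 0.192; 0.0398 with only the 4 arrays), with EREG at 1.48 and CCL2 at -1.65. The differences of all genes in HBEC correlated with those in BEAS2B at r = 0.418 (Spearman's rho 0.447) across genes, which are not independent replicates.

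**Figure D1:**
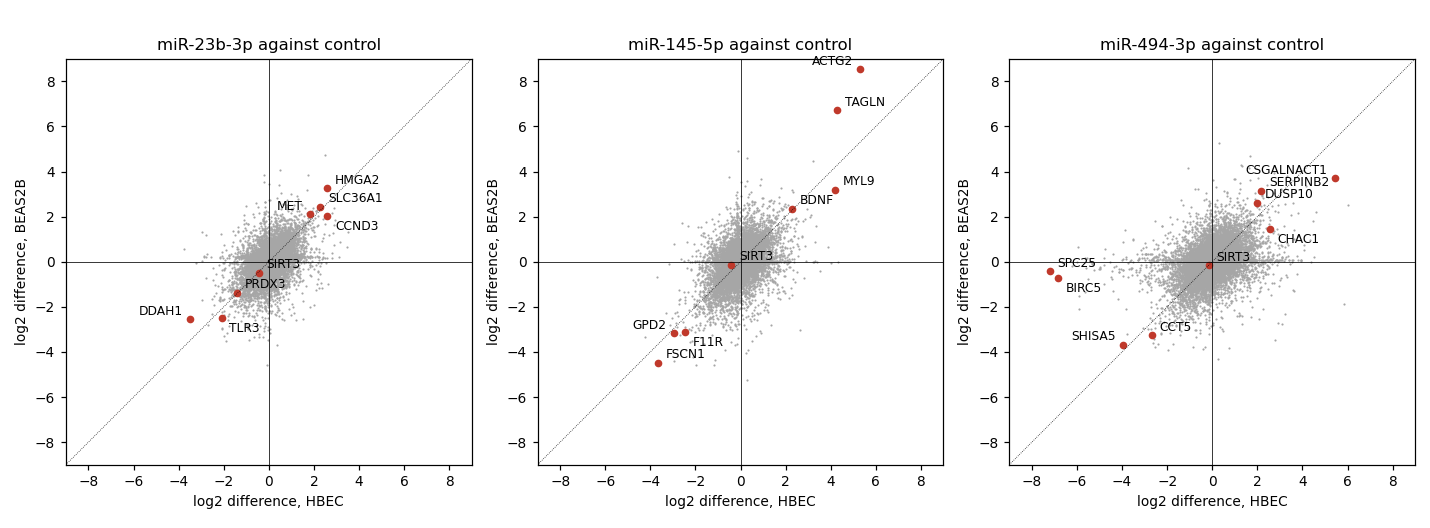
Each panel plots, for 1 mimic, the log2 difference from the control transfection in HBEC (x axis) against that in BEAS2B (y axis), with 1 grey point per named gene, red points for genes given in the text and a dotted line of equal differences. Values below the limit of well above background are drawn as measured; after miR-145-5p TAGLN (4.28 and 6.71) lies at the upper right and FSCN1 (-3.66 and -4.48) at the lower left, and after miR-494-3p BIRC5 (-6.84 and -0.72) lies far to the left.

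After the miR-145-5p mimic, FSCN1, which bundles actin filaments in protrusions, fell 16.8-fold (-4.07 ± 0.31, adjusted p = 0.0486). The junction protein F11R fell by 2.78 (SE 0.22) and the mitochondrial glycerol phosphate dehydrogenase GPD2 fell by 3.05 on the log2 scale. The neurotrophin BDNF rose by 2.32 ± 0.18. ACTG2, a smooth muscle actin, was higher by 5.32 in HBEC and at least 87.9-fold higher in BEAS2B. TAGLN, an actin-binding protein of smooth muscle, lay at 5.50 ± 0.57 and MYL9, a myosin light chain, at 3.71 ± 0.44. None of these 3 passed the test (adjusted p = 0.069, 0.0616 and 0.068). In all, limma called 4 genes higher and 18 lower among 24908, with 3881 at an unadjusted p under 0.05. By size, 278 genes were at least 2-fold higher and 356 at least 2-fold lower in both cell types (44.1 and 53 expected), and 74 moved in opposite directions. In the simulation 208 genes given no change moved the same way, against 634 here. The call of 22 genes is fragile: leaving out any 1 of the 8 arrays gave 0 genes, while the filter to probes well above background on all 8 arrays gave 512.

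Among the genes that fell after miR-145-5p were TMEM9B (-2.96), ACBD5, which tethers peroxisomes to the endoplasmic reticulum (-2.85), and the small Cajal body RNA SCARNA8 (-2.69). ABRACL (-2.60), DTD1 (-2.60), DENND5B (-2.57) and PAFAH1B2 (-2.25) also fell, all with adjusted p = 0.0486. A second DENND5B probe lay at 0.46, and 2 other PAFAH1B2 probes at 1.29 and -0.89. The second probes of F11R (-2.05), ACBD5 (-2.83) and GPD2 (-1.37) had the same sign. BANF1 rose by 2.05 and CYRIB, a regulator of RAC1, rose by 1.75. Both were at least 2-fold higher after every mimic in both cell types, and against the mean of the other 2 mimics BANF1 lay at -0.02 and CYRIB at -0.05. SCARNA8 was likewise at least 2-fold lower after every mimic. Further genes above the control that did not pass were SPOCD1 at 3.84 and MSRB3 at 2.70. MSANTD3-TMEFF1 was at least 4.13-fold higher in HBEC, and RTL5 at least 4.01-fold higher in BEAS2B. As measured, MSRB3 and MSANTD3-TMEFF1 were at least 2-fold higher after every mimic in both cell types. ACTG2 was well above background on the HBEC control array but not on that of BEAS2B. A second ACTG2 probe was not well above background on any array. Both TAGLN probes gave like values (5.50 and 5.86). FSCN1 was read by a probe on chromosome 7, 5646220 to 5646279, TAGLN on chromosome 11, 117075155 to 117075214 (hg19). F11R was read on chromosome 1, 160966033 to 160966092, and BDNF on chromosome 11, 27679900 to 27679959 (hg19).

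Published targets of miR-145-5p shifted down: the median of 39 members was -0.29 (camera adjusted p = 3.6e-04; adjusted p = 0.966 with an estimated correlation). Of these 3 fell and 0 rose over all genes, and adjusted over the list alone 14 fell and 2 rose. FSCN1 was the lowest of the 39, followed by PODXL, a sialomucin, at -2.98 ± 0.87, F11R, and ADD3, an adducin of the membrane skeleton, at -1.93 ± 0.19. Without the HBEC array of the mimic the median was -0.48. NRF2 and oxidative stress genes also shifted down (median -0.26, adjusted p = 0.00248; adjusted p = 0.966 with an estimated correlation). Of 28 members 1 fell over all genes and 2 over the list alone. The fallen gene was PGD, of the pentose phosphate pathway (-1.66 ± 0.13), and HMOX1, heme oxygenase, lay at -1.21. Interferon-stimulated genes had a median of -0.29 (adjusted p = 0.0087; adjusted p = 0.966 with an estimated correlation), with DTX3L at -1.32, EPSTI1 at -1.39 and OAS2 at -1.20. Those 3 genes were also below the control after the other 2 mimics in both cell types. The list's median was -0.218 in HBEC and -0.4 in BEAS2B. It was 0.085 and -0.427 after miR-23b-3p, and 0.323 and 0.023 after miR-494-3p. Of 40 members 0 fell over all genes and 1 over the list alone after miR-145-5p. The median was -0.45 without the HBEC control array. This last shift was lost without the BEAS2B control array (median -0.05, adjusted p = 0.849), without the HBEC array of the mimic (-0.22, adjusted p = 0.0753) and with no replicate block (adjusted p = 0.134).

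Smooth muscle contractile and actin cytoskeleton genes moved both ways after miR-145-5p: over the list alone 10 of 32 rose and 6 fell. The median of 0.31 was no call (adjusted p = 0.192; 0.0259 with no filter), and it was 0.17 without the BEAS2B array of the mimic. Over all genes 1 fell, FSCN1, and 0 rose. Of the sirtuins, SIRT5, a mitochondrial desuccinylase, lay at -1.91 ± 0.24 (adjusted p = 0.071) and fell when adjusted over the list alone. SIRT3 lay at -0.28 ± 0.15 (adjusted p = 0.46), with -0.41 in HBEC and -0.14 in BEAS2B. Against the other 2 mimics SIRT3 lay at 0.03. Against the control SIRT1 lay at -0.37 and SIRT7 at 0.44. The correlation across genes between the cell types was r = 0.402 (rho 0.388).

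**Figure D2:**
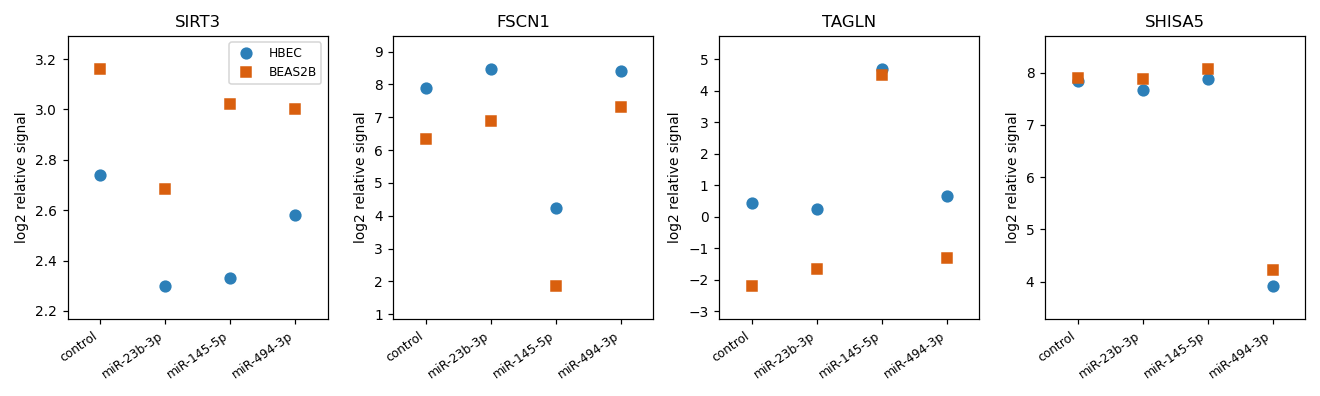
The log2 signal relative to the 75th percentile of each array (y axis) of SIRT3, FSCN1, TAGLN and SHISA5 under the 4 transfections (x axis), with 1 point per array, circles for HBEC and squares for BEAS2B. FSCN1 is lowest and TAGLN highest after miR-145-5p in both cell types, SHISA5 is lowest after miR-494-3p in both, and SIRT3 spans a narrow range.

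After the miR-494-3p mimic, SHISA5, a p53-inducible protein of the endoplasmic reticulum, fell 14.0-fold (-3.81 ± 0.14, adjusted p = 0.0222), the largest fall of the 22 called. USB1, an exonuclease that trims U6 RNA, fell by 3.02, and POLR3G, a subunit of RNA polymerase III, fell by 3.01. CCT5, of the cytosolic chaperonin, fell at least 6.68-fold, being not well above background after the mimic. MSANTD3-TMEFF1 rose, at least 8.26-fold in HBEC and by 3.80 in BEAS2B, and DUSP10, a phosphatase of stress kinases, rose by 2.29 ± 0.19. The chondroitin synthesis enzyme CSGALNACT1 was at least 9.43-fold higher in HBEC and higher by 3.69 in BEAS2B, without passing (adjusted p = 0.0526). As measured, CSGALNACT1 was at least 2-fold higher after every mimic in both cell types, though not well above background on the HBEC control array. In all, limma called 8 genes higher and 22 lower among 24908, with 4960 at an unadjusted p under 0.05. By size, 366 genes were at least 2-fold higher and 431 at least 2-fold lower in both cell types (84.6 and 91.9 expected), and 123 moved in opposite directions. In the simulation 239 genes given no change moved the same way, against 797 here. Leaving out 1 array moved the count of 30 to 0 in 7 of 8 cases, and to 215 without the BEAS2B array of the mimic. The filter to probes well above background on all 8 arrays gave 924.

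Further genes that fell after miR-494-3p were NMI (-2.85), HMGN5, a nucleosome-binding protein (-2.75), and TMEM182 (-2.64). GALNT2, which starts O-linked glycans (-2.63), the fatty acid-binding protein FABP5 (-2.62) and TGOLN2, of the trans-Golgi (-2.54), fell too, all with adjusted p between 0.0392 and 0.0487. All 3 FABP5 probes lay between -2.67 and -2.61. For SHISA5, 1 other probe gave -3.92 and 2 lay near 0, at -0.04 and -0.07, and a second USB1 probe lay at -0.13. PTPMT1 rose by 2.32, LZTFL1 by 2.22, BANF1 by 2.06, CYRIB by 1.82 and NRBF2, of the autophagy PI3-kinase complex, by 1.72. These 5 genes and MSANTD3-TMEFF1 were at least 2-fold higher after every mimic in both cell types, and against the mean of the other 2 mimics BANF1 lay at -0.02. FOXQ1, at 4.15 in HBEC and at least 8.36-fold higher in BEAS2B, and SLC2A14, a glucose transporter, at 3.38, did not pass. SLC2A14 was also at least 2-fold higher after every mimic in both cell types. SHISA5 was read on chromosome 3, 48509277 to 48509336 (hg19). CCT5 was read on chromosome 5, 10265930 to 10265989, and DUSP10 on chromosome 1, 221875773 to 221875832 (hg19). SIRT3 lay at -0.16 ± 0.15 (adjusted p = 0.593; -0.16 in each cell type; 0.21 against the other 2 mimics) and its second probe at -0.05. SIRT5 lay at -1.04, SIRT4 at 0.88, SIRT7 at 0.68 and SIRT1 at -0.44, and 0 of 7 sirtuins passed, over all genes or over the list alone.

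Mitosis and G2/M genes separated the cell types after miR-494-3p. In HBEC, 41 of 42 members were at least 2-fold below the control, with a median of -4.02 (-3.64 with the 16 members not well above background set to their bound, and -1.83 with normexp background). In BEAS2B this held for 2 of 42, with a median of -0.03. The difference between the cell types was not tested. SPC25, of the kinetochore, was at least 32.4-fold lower in HBEC and lay at -0.42 in BEAS2B. HJURP, which loads centromeric histone, was at least 102-fold lower in HBEC and lay at -0.02 in BEAS2B. BIRC5, of the chromosomal passenger complex, lay at -6.84 and -0.72. KIF4A, a mitotic kinesin, was at least 14.4-fold lower in HBEC and lay at -1.54 in BEAS2B. For the cell types together the median was -2.13 (camera adjusted p = 8.8e-08; adjusted p = 0.966 with an estimated correlation). Of 42 members 0 fell over all genes or over the list alone, and without the HBEC array of the mimic the median was 0.04 (adjusted p = 0.8). Without the BEAS2B array of the mimic it was -4.15. DNA replication and G1/S genes had a median of -1.39 in HBEC and 0.17 in BEAS2B, -0.64 together (adjusted p = 0.00121; adjusted p = 0.993 with an estimated correlation). In HBEC, RRM2, of ribonucleotide reductase, was at least 20.8-fold and DTL at least 10.7-fold lower, GINS2 lay at -3.39 and HELLS at -2.47. For the cell types together, a dimmer RRM2 probe, measured on all arrays, lay at 0.05. Of 40 members 0 fell over all genes and 2 over the list alone. That shift was lost with no replicate block (adjusted p = 0.134), without the HBEC control array (median -0.42, adjusted p = 0.0575) and without the HBEC array of the mimic (0.18, adjusted p = 0.446), and the median was -1.43 without the BEAS2B array of the mimic.

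**Figure D3:**
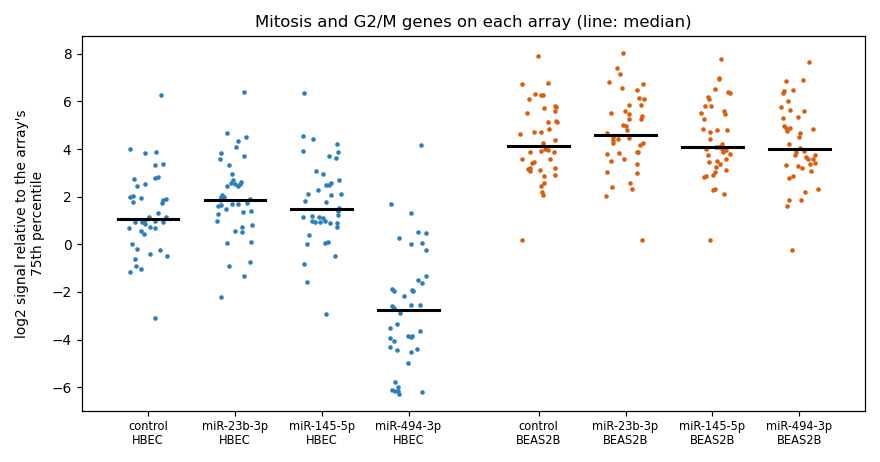
Each point is 1 of the 42 measured mitosis and G2/M genes on 1 array (x axis: transfection and cell type), as log2 signal relative to the 75th percentile of that array (y axis), and the black line is the median of the 42. The HBEC median is -2.77 after miR-494-3p against 1.08, 1.88 and 1.47 on the other HBEC arrays, and the BEAS2B medians are 4.12, 4.60, 4.08 and 4.0.

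Stress and lipid genes shifted up after miR-494-3p. Genes of the unfolded protein and integrated stress response had a median of 0.52 (adjusted p = 8.4e-05; adjusted p = 0.966 with an estimated correlation), and 8 of 30 rose over the list alone. CHAC1, which degrades glutathione, lay at 2.55 in HBEC and 1.44 in BEAS2B, PPP1R15A, which restores translation after stress, at 1.36 ± 0.16 and SEL1L at 1.36. Without the BEAS2B array of the mimic this median was 0.21 (adjusted p = 0.0836), and without the HBEC array 0.93. Cholesterol and fatty acid synthesis genes had a median of 0.47 (adjusted p = 8.4e-05; adjusted p = 0.966 with an estimated correlation), and 9 of 31 rose over the list alone. INSIG2, which holds back the activation of sterol-regulated transcription, lay at 1.24 ± 0.18 and INSIG1 at 1.01 ± 0.21. Mitophagy and autophagy genes had a median of 0.35 (adjusted p = 0.00771; adjusted p = 0.966 with an estimated correlation), and 3 of 27 rose over the list alone. PINK1, a kinase that marks damaged mitochondria, lay at 1.43 ± 0.23, ULK1, which starts autophagy, at 1.26 and WIPI1 at 1.14. This shift was lost under quantile normalization (adjusted p = 0.0528) and with no replicate block (adjusted p = 0.0564). No single member of these 3 lists passed over all genes.

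Published targets of miR-494-3p shifted down, with a median of -0.37 over 25 members (adjusted p = 0.0109; adjusted p = 0.966 with an estimated correlation). Of these 0 fell over all genes and 1 over the list alone. ROCK1, a kinase of actomyosin contraction, lay at -0.99 ± 0.15, BMI1, a Polycomb protein, at -1.02, and RAD23B at -0.87 in HBEC and -2.69 in BEAS2B. The cytokine LIF lay at 2.62 in HBEC and 0.12 in BEAS2B. The shift was lost with no replicate block (adjusted p = 0.11) and without the BEAS2B array of the mimic (median -0.27, adjusted p = 0.251). Squamous differentiation markers had a median of 0.65 (adjusted p = 0.0297; adjusted p = 0.966 with an estimated correlation), 1.02 in HBEC. In BEAS2B 15 of the 29 members were not well above background on any array, so the BEAS2B part of this call rests mostly on background and no median is given for it. The kallikrein KLK10 lay at 2.93 in HBEC and 0.76 in BEAS2B. KLK7 and SERPINB3, not well above background in BEAS2B, lay at 2.24 and -1.53 in HBEC. Of 29 members 0 passed over all genes, and 2 rose and 1 fell over the list alone. It was lost with no replicate block (adjusted p = 0.746), without the HBEC control array (median 0.35, adjusted p = 0.4) and without the HBEC array of the mimic (0.34, adjusted p = 0.169), and the median was 1.01 without the BEAS2B array of the mimic. Senescence-associated secreted factors had a median of 0.39 without a call (adjusted p = 0.0958), and 1 of 34 rose over the list alone. They did pass with no filter (adjusted p = 0.0232), without the HBEC control array (0.0421) and without the HBEC array of the mimic (median 0.52, adjusted p = 0.00181), and the median was 0.13 without the BEAS2B array of the mimic. SERPINB2 lay at 2.17 in HBEC and was at least 8.74-fold higher in BEAS2B. MMP1 lay at 0.31 in HBEC and was at least 14.7-fold higher in BEAS2B, while CSF2 lay at 2.12 and CCL2 at -2.02. The correlation across genes between the cell types was r = 0.356 (rho 0.394). Markers of alveolar, endothelial, immune and fibroblast cells gave no call after any mimic (medians -0.16, -0.23 and 0.19; adjusted p = 0.444, 0.282 and 0.695).

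HBEC and BEAS2B differed in most genes measured. Keratins and squamous genes were higher in HBEC: the basal keratin KRT5 was at least 6527-fold and KRT6B at least 7663-fold higher. The cornified envelope gene SPRR2A was at least 7137-fold and the calprotectin subunit S100A8 at least 9148-fold higher, none of these 4 being well above background on a BEAS2B array. KRT19, measured on all arrays, stood at 10.63 ± 0.12 (SD, n = 4) in HBEC and -2.80 ± 0.17 in BEAS2B (adjusted p = 6.6e-06). In BEAS2B, PMP22, a membrane protein of Schwann cells, was higher, with a log2 difference of -8.70 (5.67 ± 0.42 against -3.03 ± 0.48; adjusted p = 9.4e-06). BEX1 stood at 6.77 ± 0.39 against -1.56 ± 0.45, and the homeobox genes HOXC9, HOXC6 and HOXC8 were at least 210-fold, 119-fold and 53.9-fold higher. With the transfection in the fit, limma called 7880 genes higher in HBEC and 8279 higher in BEAS2B among 24908. The 4 arrays of a cell type were its different transfections, not repeats of the same transfection. The p-values and SDs thus reflect how constant values were across transfections. Variation between donors or cultures of a cell type was not measured. The labels give the cell types different media, and each lay in a slide row of its own, so cell type, medium and row cannot be told apart.

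Other genes higher in HBEC were S100A9, KRT6C, KRT6A, CRCT1 and IL1RN. Other genes higher in BEAS2B were GREM1, a BMP antagonist (4.95 ± 0.86, against -5.42 in HBEC with 1 of 4 arrays well above background), PTX3, EGFLAM (at least 195-fold) and ELOVL2 (at least 169-fold). The brighter of the 2 IL1RN probes stands for the gene here, while with the filter on all 8 arrays, which keeps the other, IL1RN differed by 4.46. KRT5 was read on chromosome 12, 52908622 to 52908681, KRT19 on chromosome 17, 39679918 to 39679977, and PMP22 on chromosome 17, 15133208 to 15133267 (hg19).

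Of the 33 lists, 15 shifted between the cell types. Higher in HBEC were squamous differentiation markers (median 7.04, or 6.72 with members not well above background in a cell type at their bound, 28 of 29 higher; adjusted p = 9.4e-13; adjusted p = 0.458 with an estimated correlation) and airway basal cell markers (6.0, or 5.54 at the bounds, 19 of 24 higher; adjusted p = 3.3e-07; adjusted p = 0.458 with an estimated correlation). So were epithelial junction genes (4.97, 27 of 31 higher; adjusted p = 7.2e-11; adjusted p = 0.57 with an estimated correlation), among them the desmosomal cadherins DSG3 (at least 954-fold) and DSC2 (at least 340-fold). Airway secretory cell markers had a median of 1.56, or 0.70 at the bounds (15 of 20 higher; adjusted p = 7.7e-05; adjusted p = 0.458 with an estimated correlation), with LCN2 at least 916-fold higher. p53 target genes had a median of 1.20 (21 of 30 higher; adjusted p = 4.98e-04; adjusted p = 0.57 with an estimated correlation), with PERP at 5.85 and BTG2 at 3.18. Higher in BEAS2B were mitosis and G2/M genes (median -3.94, 42 of 42 higher in BEAS2B; adjusted p = 2.1e-07; adjusted p = 0.609 with an estimated correlation), whose median was -2.88 without the HBEC array of miR-494-3p. DNA replication and G1/S genes were also higher in BEAS2B (-3.07, 38 of 40; adjusted p = 2.0e-09; adjusted p = 0.609 with an estimated correlation). Interferon-stimulated genes had a median of -1.88 (34 of 40 higher in BEAS2B; adjusted p = 5.7e-08; adjusted p = 0.57 with an estimated correlation), with RSAD2 at -6.05 and IFIT1 at -5.83. Mesenchymal and matrix genes had a median of -2.14, or -2.06 at the bounds (21 of 29; adjusted p = 0.00279; adjusted p = 0.57 with an estimated correlation), with ZEB2 at least 32.8-fold higher in BEAS2B and the cadherin CDH2 at -5.17. The counts over the lists alone were the same for these 9 lists. Of the sirtuins, SIRT1 was higher in BEAS2B (log2 difference -1.22 ± 0.11, adjusted p = 5.1e-04), as were SIRT4 (-0.78) and SIRT3 (-0.48 ± 0.11, adjusted p = 0.0114), without a shift of the list of 7 (adjusted p = 0.493).

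Without the bounds, the 6 further lists with a shift had smaller medians. Higher in HBEC were glycolysis and hypoxia genes, with a median of 1.06 (23 of 34 higher; adjusted p = 5.8e-04; adjusted p = 0.609 with an estimated correlation), and inflammatory genes of the NF-kappaB pathway, with 1.02, or 0.89 at the bounds (23 of 38; adjusted p = 0.0277; adjusted p = 0.609 with an estimated correlation). Cytosolic ribosomal protein genes had a median of 0.21 (13 of 45 higher, 3 over the list alone; adjusted p = 0.0103; adjusted p = 0.721 with an estimated correlation). Mitophagy and autophagy genes (0.57, 16 of 27 higher; adjusted p = 0.042) and smooth muscle and actin genes (0.43, 17 of 32; adjusted p = 0.0421) were also higher in HBEC, each with an adjusted p = 0.57 with an estimated correlation. Genes of the unfolded protein and integrated stress response were higher in BEAS2B (median -0.79, 20 of 30, 21 over the list alone; adjusted p = 0.00896; adjusted p = 0.609 with an estimated correlation).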

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

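The 3 tests of seed words, the test of a word of the control oligonucleotide and the splits of the arrays were planned before their results were seen. The tests of a response shared by the mimics, of array scaling, of the control array and of the single culture were chosen after the results were seen. So was the rank of words scaled by the square root of their number of genes.

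More genes were at least 2-fold lower in both cell types than expected if these were independent: 264 against 38.6 after miR-23b-3p, 356 against 53 after miR-145-5p and 431 against 91.9 after miR-494-3p; a simulation with the residual spread of the arrays gave more than that product: 218, 208 and 239 genes without a change went the same way, up or down, against 517, 634 and 797 measured. Unlike mimics correlated across the cell types at 0.202 at most, while like mimics correlated at 0.356 or more. This argues against a response shared by all 3 mimics, relative to the control, as the whole explanation. A response that the control RNA also raised would cancel in these differences, so a response to any transfected duplex could not be tested. Repression through the seed may account for part of the excess. Among 7-base words of the same A and T content, the percent with a mean change as low or lower in the array probes was 0.616 or less for AATGTGA, the site of miR-23b-3p. For AACTGGA, the site of miR-145-5p, it was 0.375 in HBEC and 0.2 in BEAS2B, and for AATGTGA 0.308 and 0.616. For ATGTTTC, the site of miR-494-3p, it was 1.89 in HBEC and 0.115 in BEAS2B, which leaves the question open against the limit of 1 set beforehand. Scaled by the square root of the number of genes, the 3 words ranked 2, 2 and 1 of 13882 in the mean of the cell types. The rank for miR-494-3p in HBEC alone was 13. A probe of 60 bases samples only part of a 3' UTR.

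Mitosis and G2/M genes had a median of -4.02 in HBEC and -0.03 in BEAS2B after miR-494-3p. Array scaling was tested with quantile and median scaling, under which the HBEC median was -4.008 or lower; normexp background correction, at first part of this test, gave -1.83 and was left out after that value was seen, because it alters the background and not the scale. Between these settings the median of all genes in HBEC stayed from 0.01 to 0.048. An unusual control array was argued against by the median of -4.525 against the other 2 mimics. An event of the single HBEC culture with this mimic could equally give the pattern, as there was 1 such culture, and a response of primary cells to the mimic stays an untested biological explanation.

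After all 3 mimics, 42 genes were at least 2-fold higher and 11 at least 2-fold lower in both cell types, against 1.938 and 0.633 expected if the cell types were independent. The simulation without a change, which exceeded this product for single mimics, was not run for these counts. All 3 mimics share 1 control array per cell type, so an effect of the negative control RNA on these arrays may give the pattern. The word lowest in the HBEC control, CTGCGTA, in 22 genes, lay at 0.18% from the bottom in BEAS2B, between the limits of 0.1% and 5% set beforehand, while the word lowest in the BEAS2B control lay at 87.2% in HBEC. An effect through a seed of the control RNA and a response of the cells to all 3 mimics cannot be told apart here.

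For the comparison of HBEC with BEAS2B, the 8 arrays were split into 4 and 4 in all 35 ways, with cell type alone in the model. The real split gave 13846 genes, and the highest other gave 1. Every other split put arrays of both cell types on each side, so the difference between the cell types entered its residual spread. The 4 arrays of a cell type were its 4 transfections. The splits therefore cannot decide whether chance differences between cultures contributed.

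Among 110 groups of 4 arrays, 7 held an array far from the others by its gap over the range, where chance flags about 1 in 20 groups, or 5.5. The HBEC control array had 28954 probes well above background against 29484 to 29593 (gap over range 0.83). KRT5 on the BEAS2B control array was -4.24 against -6.34 to -6.15 (0.911), and was not well above background on any of these arrays. GREM1 was -3.30 on the HBEC array of miR-494-3p against -6.28 to -5.84 (0.853), and ELOVL2 -5.12 on the HBEC array of miR-145-5p against -6.03 to -5.89 (0.851). Published miR-494-3p targets had a median of 2.30 on the HBEC array of miR-23b-3p against 1.92 to 1.95 (0.914). DNA replication genes had a median of 4.12 on the BEAS2B array of miR-494-3p against 4.24 to 4.25 (0.906). Mesenchymal and matrix genes had one of 0.56 on the HBEC array of miR-494-3p against -0.23 to -0.20 (0.963). The median difference of DNA replication and G1/S genes after miR-494-3p had opposite signs in the cell types (-1.39 in HBEC and 0.17 in BEAS2B, a difference of -1.565 that was not tested). A rise in BEAS2B is not shown, as 15 of 40 members were lower in both cell types and the median level in BEAS2B was lower than on the control array.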

How the results depend on the processing

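The counts at an unadjusted p were chosen after the results were seen; the other alternatives were planned. The cause of each move was not tested unless it is given.

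Of 3530 values under the alternatives, for 195 pairs of a named gene and a comparison, 3515 kept their sign. Most of these genes were picked for large differences on the same arrays, so a kept sign says little about how firm they are. Of the same values, 356 lost a call and 133 gained one. The number of genes past the threshold depended on the processing for every mimic. After miR-23b-3p, limma called 0 genes (3615 unadjusted), but 172 with normexp background, 162 with the filter on all 8 arrays and 118 with trend and robust estimation. After miR-145-5p the 22 genes became 447 with normexp background, 36 with quantile normalization, 512 with the filter on all 8 arrays, 440 with trend and robust estimation and 409 against the mean of the other 2 mimics. They became 0 with no filter, with the mean of a gene's probes, with no replicate block, with only the 4 arrays of the mimic and the control, and without any 1 array (0 to 0), where 3881 genes had an unadjusted p under 0.05 in limma on all arrays. After miR-494-3p the 30 genes became 815 with normexp background, 67 with quantile normalization, 924 with the filter on all 8 arrays, 56 with the deposited values, 725 with trend and robust estimation and 733 against the other 2 mimics. They became 0 with no filter, with no replicate block and with only the 4 arrays (4960 unadjusted on all arrays in limma), and ranged from 0 to 215 when 1 array was left out, 215 without the BEAS2B array of miR-494-3p. With no replicate block the difference between the cell types enters the residual spread, and with 4 arrays 1 residual degree of freedom is left. Where an array left out leaves a transfection with 1 array, that array is assumed to vary like the others. Between HBEC and BEAS2B the count of 16159 stayed between 12906 and 16364, and between 13580 and 15123 when 1 array was left out.

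Gene lists past the threshold after miR-23b-3p were 2, and 7 with normexp background, 4 with median scaling, 5 with no filter, 6 with only the 4 arrays, and 2 to 8 when 1 array was left out: 8 without the HBEC control array, 6 without the BEAS2B and 4 without the HBEC array of miR-23b-3p, and 4 without either array of miR-494-3p. After miR-145-5p the 3 lists became 6 with no filter and 3 to 5 when 1 array was left out, 5 without the BEAS2B array of miR-145-5p. After miR-494-3p the 7 lists became 11 with normexp background, 3 with no replicate block and 6 to 10 when 1 array was left out. With an estimated correlation and with fry the counts were 0 for each mimic; between the cell types the 15 lists became 0 with an estimated correlation and 27 with fry, which sets no list against other genes.

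Genes at least 2-fold the same way in both cell types numbered 517 after miR-23b-3p, 634 after miR-145-5p and 797 after miR-494-3p. In that order they were 161, 222 and 257 with normexp background, whose offset shrinks differences of dim genes, and 321, 412 and 505 with the filter on all 8 arrays, which tests fewer genes. The correlations between the cell types of 0.418, 0.402 and 0.356 became 0.602, 0.572 and 0.478 with normexp background, 0.595, 0.557 and 0.478 with the filter on all 8 arrays and 0.229, 0.251 and 0.246 with no filter.

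The median of published miR-23b-3p targets, -0.054, was 0.033 with median scaling, 0.037 with the filter on all 8 arrays, -0.165 to 0.052 when 1 array was left out and -0.249 (adjusted p = 0.0472) against the other 2 mimics. That of published miR-145-5p targets, -0.293, lost its call with an estimated correlation (adjusted p = 0.966) and with fry (adjusted p = 0.141), at the same median, and ranged from -0.480 to -0.293 when 1 array was left out. That of published miR-494-3p targets, -0.373, lost its call with no replicate block (adjusted p = 0.11), an estimated correlation (0.966) and fry (0.378), and ranged from -0.534 to -0.186 when 1 array or cell type was left out (-0.265, adjusted p = 0.251, without the BEAS2B array of miR-494-3p).

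Values that reversed were AKR1C3 after miR-23b-3p, 0.001 with normexp background and -2.193 to 0.163 when 1 array was left out, and the list of glycolysis and hypoxia genes after miR-23b-3p, 0.049 with median scaling and -0.132 to 0.022 when 1 array was left out. RRM2 after miR-494-3p was 0.049 with the filter on all 8 arrays, where another probe stands for it. HJURP (-6.739 to 0.04 over the arrays left out), the mitosis list (-4.151 to 0.041) and the replication list (-1.426 to 0.184) reversed after miR-494-3p. These reversals came without the HBEC array of miR-494-3p. BEAS2B then gives the mimic's only array, set against a control level that draws on both cell types. Measured within BEAS2B, the mitosis median was -0.033 and the replication median 0.172, and HJURP stood at 5.768 against 5.789 in the control. The reversed sign of HJURP and of the mitosis list thus came from the fit. Against the other 2 mimics, PTPMT1 was -0.109, SIRT5 1.141 and SIRT7 -0.097 after miR-23b-3p; BANF1 was -0.024, CYRIB -0.047, SIRT3 0.034, AKR1C1 0.006 and SIRT7 -0.133 after miR-145-5p; BANF1 was -0.018, SIRT3 0.208 and SIRT5 0.085 after miR-494-3p.

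The planned search for seed sites in 3' UTRs, with its alternative of 8-base sites, was not run, as no genome was used here. The signal over background limits genes near background, where the offset and the filters act most.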

Other observations

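The genes moved by all 3 mimics and the genes named here were chosen after their values were seen. Of the 11 genes at least 2-fold lower than the control after every mimic in both cell types, 8 were small RNAs of the nucleolus and the Cajal body. Their share was not tested, 4 of them are copies of SNORD116, and none of the 11 passed the test of the mean of the 3 mimics against the control. SNORA79 had a mean of -2.65 over the 3 mimics, SCARNA13 -2.49, SCARNA11 -2.37 and SCARNA8 -2.26, and SNORD116-12, SNORD116-11, SNORD116-6 and SNORD116-19 lay between -2.37 and -1.90. Among the 42 higher genes were KLF2 (2.50), a transcription factor of quiescent cells, the tight junction gene CLDN1 (2.24), CCND3 (2.17), MET (1.95), NRAS (1.54) and fibronectin, FN1 (1.47). With the mean of the mimics set against the control, limma called 0 genes (3673 at an unadjusted p under 0.05), and the differences correlated between the cell types at r = 0.371 across genes.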
